A study of Mus musculus with 4 samples.

How the data were processed

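RNA sequencing was performed on lymphatic endothelial cells sorted from the meninges of male C57BL/6J mice aged 20 to 24 months. The mice had received 5 µL of an adeno-associated virus of serotype AAV1 into the cisterna magna 4 weeks earlier. The virus carried either mouse VEGF-C, a growth factor for lymphatic vessels, or the fluorescent protein eGFP as control, each under the CMV promoter. Cells were sorted as live single cells negative for CD45 and positive for CD31 and podoplanin, and each library came from the pooled meninges of 10 mice. There were 2 libraries per group. Per the labels' protocols, RNA was extracted with a kit for very small inputs and amplified linearly before the libraries were made.

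The authors deposited 1 table of 9114 genes by 4 libraries. Per the submitters' processing notes, reads were handled with FastQC, Trimmomatic, Salmon and DESeq2 on the mm10 build, with no versions given. The deposited values are a signal in the form of normalised read counts: every value in a library is a whole multiple of the smallest value above 0 in that library (100% of values whole within 0.001), so whole reads were recovered by division. Size factors recomputed from the recovered reads by the median of ratios over the genes of the table equalled the deposited scaling, at 1.117 for eGFP 1, 0.936 for eGFP 2, 0.936 for mVEGF-C 1 and 1.076 for mVEGF-C 2. The recovered depth was 27618967, 25610683, 26754001 and 28632461 reads in that order. These are reads on the genes of the table only. PCR duplicates cannot be told from independent molecules here, so counting intervals would cover counting error only, and none is given because the spread between libraries is far larger (chi-square per degree of freedom of 520.7 between the mVEGF-C libraries and 457.8 between the eGFP libraries).

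The genes of the table had been limited by replicate agreement, as read from the values. The standard deviation of log2(reads + 1) within a group never exceeded 2.999 in the mVEGF-C pair or 2.000 in the eGFP pair, so 2 libraries of a group differed by at most 4.24 and 2.83 on the log2 scale, whereas libraries of different groups differed by up to 10.69. No gene was at 0 in more than 1 library, and 82 genes were at 0 in 1. Genes outside these limits are not analysed here. Because the limits were set within the groups, the spread between replicates is understated, and a gene with a large difference between libraries could stay in the table only if that difference followed the groups or was within the limits. The p-values below are therefore too small by an amount that the table does not give.

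Gene names were used as in the table for 7935 rows. Of 1146 rows named by an Ensembl identifier, 1098 were given a symbol. A further 13 mitochondrial rows were matched by position and 9 by a synonym, and 11 found no match. Coordinates, 1-based, are from GENCODE vM21 on the assembly GRCm38, which is mm10, and were found for 9030 rows (99.1%). The strand setting and the annotation of the authors' counting are not given in the sources used here.

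The main comparison, mVEGF-C against eGFP, was made in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend of the variance on expression) on log2(normalised count + 1), two-sided, for the 9063 genes with a mean of at least 10 over the 4 libraries. A gene is said to be called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that log2 scale, which understates the change of low genes, and are given as mVEGF-C minus eGFP with the standard error. The fit left 2 residual degrees of freedom, and the moderated variance came entirely from the trend because the estimated prior degrees of freedom were infinite. A gene's own spread between replicates therefore did not enter its p-value. Group values are mean ± SD over 2 libraries. Library measures were compared by an exact two-sided permutation test, whose smallest possible p with 2 against 2 libraries is 0.333. Each replicate number was borne by 1 library of each group.

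The main test, the alternatives, 36 gene lists with 920 entries and the rule for the genes named were fixed before the data were examined; alternatives added later are given as such. The design had assumed normalised values, as found. Of the list entries, 544 had a row, so many lists were tested only in part. For example, 12 of 27 VEGF and ERK response genes, 9 of 18 Notch genes and 15 of 36 cell cycle genes were tested. Lists with at least 5 members tested (32 lists) were compared with the other genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists. The lists were also tested with an estimated correlation, by ranks, and with fry, whose directional p asks whether the members move on balance in 1 direction and whose mixed p asks whether they change in either direction. The genes named are the sort and identity genes, the 12 highest and 12 lowest called fold changes among genes with a mean of at least 50 and groups that did not overlap, and, per list, up to 4 called members with the largest fold changes or, where none was called, the 2 with the smallest p. Of the genes to be named whatever their values, Vegfc and Ptprc are not analysed here, and some genes that the rule names are not reported here.

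Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, 3 other scalings, eBayes without trend and with robust, voom weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, each library left out in turn, and thresholds of an absolute log2 fold change of at least 1 or an adjusted p under 0.1. After the data were seen, 3 were added: a spread corrected for the selection by a truncated-normal estimate in 10 bins of expression, the limit of the eGFP pair applied to both groups, and mitochondrial rows left out. edgeR called 67 genes higher and 79 lower.

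The test was tried on counts simulated for these genes and libraries, with 100 genes changed by a log2 fold of 3 and 100 by a log2 fold of 6 among 9015 tested. limma recovered 23% and 92% of these in the right direction and called 3 unchanged genes; edgeR recovered 31% and 96% and called 5; DESeq2 recovered 55% and 100% and called 54. A planted list of 40 genes shifted by 1.5 gave a camera p of 3.85e-11, and a random list gave 0.839. Those counts carried no selection on replicate agreement, and each gene was drawn independently. The list check therefore does not cover lists with correlated members, such as the fibroblast markers with an estimated correlation of 0.357. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.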

Results

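Gene expression was measured in 4 libraries of sorted meningeal lymphatic endothelial cells from aged mice, 2 from mice given AAV1-mVEGF-C and 2 from mice given AAV1-eGFP. The depth recovered from the normalised counts lay between 25610683 and 28632461 reads per library. The groups overlapped in depth (exact permutation test, p = 0.667, with 0.333 the smallest possible p). Mitochondrial transcripts took 21.9% to 24.3% of the reads, most of it the 2 mitochondrial ribosomal RNAs at 19.96% to 22.01%. Of the 9114 genes, 9111 and 9110 were above 0 in the eGFP libraries and 9066 and 9087 in the mVEGF-C libraries (exact permutation p = 0.333, the smallest possible). The limit on replicate spread was wider in the mVEGF-C pair and left more room for a 0 there. These numbers therefore do not show a difference in detection between the groups. Across genes, the rank correlation was 0.873 within the eGFP pair, 0.823 within the mVEGF-C pair and 0.763 to 0.841 between libraries of different groups. The first principal component (51.9% of the variance) placed both eGFP libraries on 1 side and both mVEGF-C libraries on the other. The limits on replicate agreement held the 2 libraries of a group together. Neither this separation nor the correlations within the groups therefore show an effect of the groups.

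**Figure D1:**
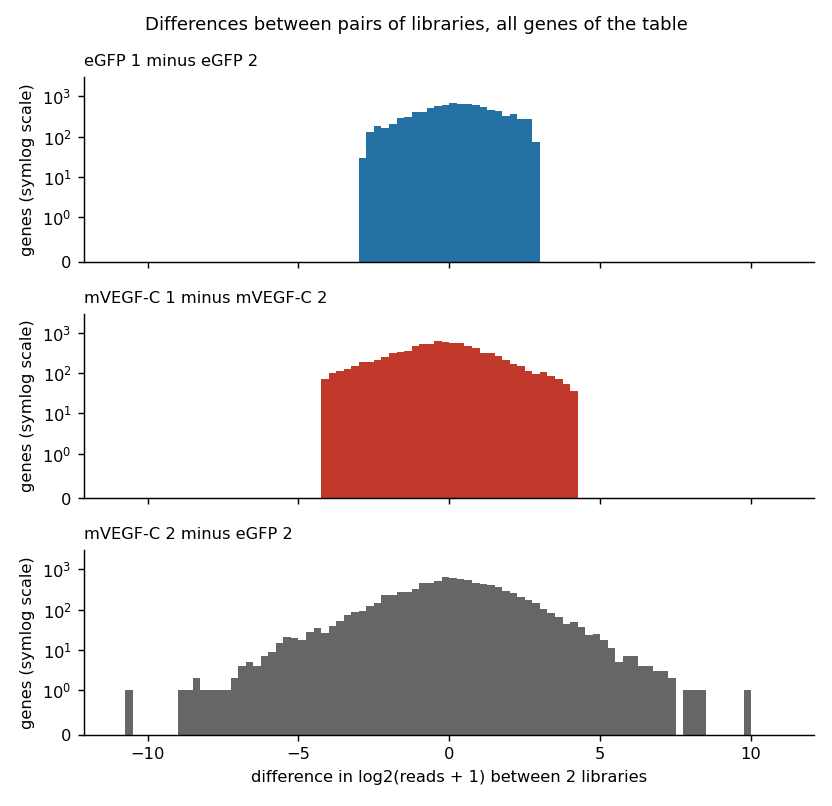
Histograms of the difference in log2(reads + 1) between 2 libraries over all genes of the table, with the number of genes on a symlog axis: eGFP 1 minus eGFP 2, mVEGF-C 1 minus mVEGF-C 2, and mVEGF-C 2 minus eGFP 2. The differences within a group end abruptly at 2.83 (eGFP) and 4.24 (mVEGF-C) on either side of 0, and those between the groups reach 10.69.

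The libraries carried the transcripts of lymphatic endothelium at high levels in both groups. Flt4, the receptor tyrosine kinase for VEGF-C (VEGFR3), ranked 18 of the 9063 genes by mean normalised count. Lyve1, a hyaluronan receptor of lymphatic vessels, ranked 20, Nrp2, the co-receptor for VEGF-C, 29, and Prox1, the transcription factor that sets lymphatic identity, 31. The sort marker Pecam1 (CD31) ranked 120 and Pdpn (podoplanin) 1399. Fibroblast markers were abundant too. The median level of the 16 meningeal fibroblast markers tested was 6894, against 10870 for the lymphatic identity and 5880 for the pan-endothelial list. All other lists of non-endothelial markers had lower medians, from 67.9 (lymphocyte) to 2328 (mural). The ranks therefore do not show that the libraries held lymphatic cells alone.

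The first question was whether VEGF-C delivery changed these receptor and identity genes, and none was called by limma. Flt4 (chromosome 11, 49609263 to 49652739) had 68707 ± 4584 normalised counts in mVEGF-C and 61487 ± 15395 in eGFP libraries (mean ± SD, n = 2 each), a log2 fold change of 0.18 with an SE of 0.22 (limma, adjusted p = 0.863). Nrp2 (chromosome 1, 62703285 to 62818695) had 55743 ± 11294 against 38298 ± 5868, with both mVEGF-C libraries above both eGFP libraries. Its log2 fold change was 0.54 with an SE of 0.27 (limma, adjusted p = 0.398). Prox1 (chromosome 1, 190118035 to 190170714) differed by 0.20, with a 95% interval of -0.36 to 0.76 (limma, adjusted p = 0.896). Lyve1 (chromosome 7, 110850607 to 110863239) differed by 0.38, with an interval of -0.07 to 0.83 (limma, adjusted p = 0.561). As for Nrp2, both mVEGF-C libraries lay above both eGFP libraries for Lyve1 and Pecam1. Groups that did not overlap, in either direction, were seen for 39.2% of all genes, against 33.3% for a pairing taken at random. For Pecam1 the difference was 0.49 (interval -0.35 to 1.32) and for Pdpn -0.11 (interval -1.64 to 1.42), with adjusted p of 0.766 and 0.987 in limma. Single libraries set the sign for 2 of these genes: Flt4 stood at -0.08 without eGFP 1 and 0.44 without eGFP 2, and Pdpn at 0.11 without mVEGF-C 1. The other 4 kept their sign but shrank without mVEGF-C 1, Nrp2 to 0.33, Prox1 to 0.03, Lyve1 to 0.19 and Pecam1 to 0.29, and grew without mVEGF-C 2, to 0.74, 0.37, 0.57 and 0.69. The intervals rest on the trend alone and are likely too narrow for the abundant genes. The SEs of Flt4, Nrp2, Prox1, Lyve1 and Pecam1 lay between 0.22 and 0.43. With the corrected spread the SE in the most abundant bin of expression was 0.571.

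Across the table, 75 genes were higher and 119 lower in the mVEGF-C libraries (limma, adjusted p under 0.05), which is 2.14% of the 9063 genes tested. At an unadjusted p under 0.05 there were 1068 genes, against medians of 890 with normal noise and 1002.5 with t noise of 3 degrees of freedom over 50 tables each, simulated with no group difference and the same limits on replicate spread. In those simulated tables a median of 16 genes were called with normal noise and 102.5 with t noise, though no group difference was present. The called genes had a median absolute log2 fold change of 4.88, against 0.79 over all genes. The 2 groups did not overlap for 192 of the 194 called genes, and for 39.2% of all genes, against 33.3% for a pairing taken at random. This lends the calls no support. For 183 of the 194 called genes the limits on replicate spread allow no other pairing of the libraries, against 262 of the 8869 genes not called. The number of calls changed with single libraries left out: without eGFP 2 it was 5 higher and 0 lower (203 and 196 at an unadjusted p under 0.05), without eGFP 1 it was 19 and 19, and without mVEGF-C 2 the lower genes numbered 188. With the spread corrected for the selection of the table's genes on replicate agreement, an alternative added after the data were seen, 6 genes were higher and 8 lower, eBayes without trend called 15 and 26, DESeq2 called 289 and 329, and edgeR called 67 and 79.

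**Figure D2:**
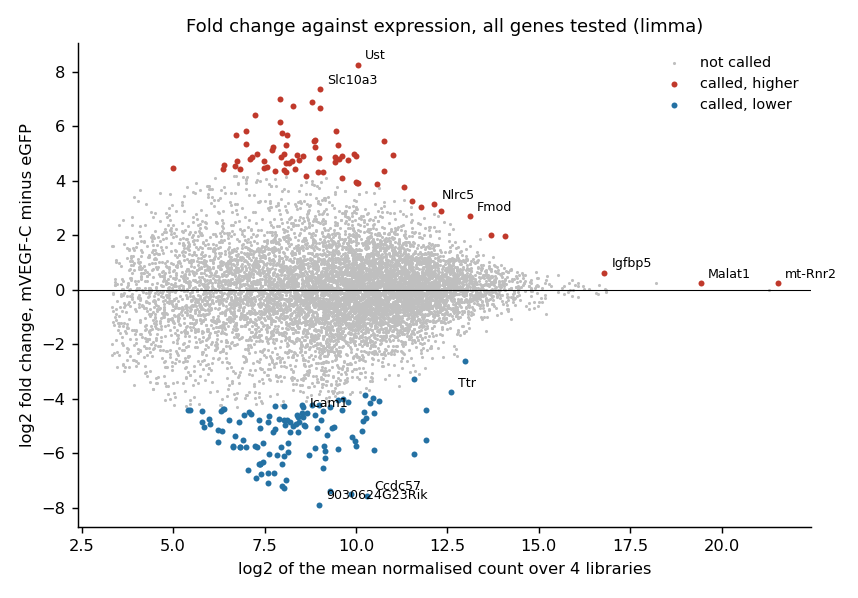
Each point is 1 of 9063 genes: the log2 fold change, mVEGF-C minus eGFP, against the log2 of the mean normalised count over the 4 libraries, with called genes in color (75 higher, 119 lower). The called genes reach from -7.88 to 8.25, and the smallest called fold changes are those of the abundant genes Igfbp5 (0.62), Malat1 (0.23) and mt-Rnr2 (0.24).

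The largest increases were in genes close to absent from the eGFP libraries. Ust (chromosome 10, 8204756 to 8518825), which encodes a sulfotransferase for chondroitin and dermatan sulfate, had 2114.5 ± 1616 normalised counts in mVEGF-C and 5.0 ± 2.0 in eGFP libraries (n = 2 each), a log2 fold change of 8.25 with an SE of 1.29 (limma, adjusted p = 7.78e-07). Slc10a3 (chromosome X, 74369217 to 74373349) had 1030 ± 963 against 5.46 ± 6.21 (log2 fold change 7.35). Sox6 (chromosome 7, 115470872 to 116038796), a SOX-family transcription factor, had 879 ± 999 against 3.76 ± 2.29 (6.87). Gmppb (chromosome 9, 108049242 to 108052801), a subunit of the enzyme that makes GDP-mannose, had 619 ± 85.2 against 5.99 ± 5.45 (6.72). The others of the 12 highest were the sodium leak channel Nalcn (7.0), Qrsl1 (6.66), Tmem81 (6.41), the pro-apoptotic BCL2-family gene Bad (6.16), the oxysterol-binding protein gene Osbpl3 (5.83), the presynaptic adhesion gene Nrxn3 (5.81), Meioc (5.75) and the histone gene Hist2h2ac (5.68), whose reads can be shared with other histone genes. Nalcn and Tmem81 were at 0 in eGFP 1, so their fitted folds depend on the pseudocount. All 12 were also called by edgeR and DESeq2. Without eGFP 2, 2 of the 12 were called (adjusted p up to 0.434), without eGFP 1, 7 were, and with the corrected spread 5 were: Ust, Slc10a3, Sox6, Gmppb and Qrsl1. Without trend, 11 were called.

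The largest decreases mirrored this, with genes expressed in eGFP and close to 0 in mVEGF-C libraries. Ccdc57 (chromosome 11, 120826529 to 120932872) had 10.7 ± 4.56 in mVEGF-C and 2519 ± 1991 in eGFP libraries (n = 2 each), a log2 fold change of -7.54 with an SE of 1.27 (limma, adjusted p = 7.11e-06). Slc39a6 (chromosome 18, 24579881 to 24603817), a zinc transporter, had 11.4 ± 10.1 against 1848 ± 395 (-7.49). Ddx39 (chromosome 8, 83715177 to 83726892), an RNA helicase, had 7.57 ± 7.69 against 1234 ± 791 (-7.38). 9030624G23Rik (chromosome 12, 24043202 to 24097246) had the lowest fold change, -7.88. The others of the 12 lowest were Gm340 (-7.28), the vesicle-transport gene Use1 (-7.20), Tbc1d5 (-7.09), the transcriptional corepressor Tle6 (-6.99), the dynein assembly gene Dnaaf5 (-6.89), Gm22304 (-6.74), Rptoros (-6.72) and Gm3248 (-6.71). Gm22304 is annotated as a small nucleolar RNA, Rptoros as antisense, and Gm3248 is a predicted gene, so their values are uncertain where reads are shared with an overlapping or similar gene. In 8 of the 12 lowest, 1 mVEGF-C library was at 0, so the fitted fold depends on the pseudocount. All 12 were called by edgeR and DESeq2 too, but without eGFP 2 none was (adjusted p of 0.0593 to 0.592 in limma), without eGFP 1, 7 were, with the corrected spread 4 were, and without trend 10 were.

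**Figure D3:**
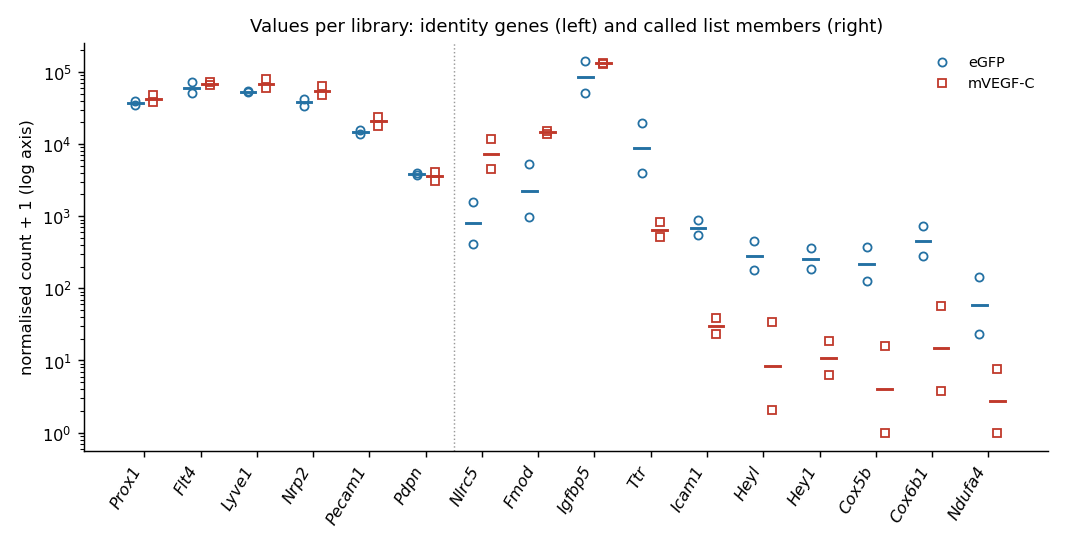
Normalised count + 1 per library on a log axis, circles for the 2 eGFP and squares for the 2 mVEGF-C libraries, with bars at the mean of the log values. Among the identity genes on the left, the groups overlap for Prox1, Flt4 and Pdpn. For Lyve1, Nrp2 and Pecam1 both mVEGF-C libraries lie above both eGFP libraries. Among the 10 called list members shown on the right the groups separate except for Igfbp5, where eGFP 1 (140594) lies above both mVEGF-C libraries (132701 and 129644).

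In the lists of lymphatic, endothelial, VEGF, junction, matrix, integrin and guidance genes no member was called in the main limma fit. Of 23 lymphatic identity genes tested, 17 had fold changes above 0, with a median of 0.27 (camera in limma, adjusted p = 0.217). Those with the smallest p were Itga9, an integrin of lymphatic valves, at 1.29 ± 0.57 (SE) and Ecscr at 1.40 ± 0.65, neither called by limma (adjusted p = 0.293 and 0.332). Of 18 pan-endothelial genes 11 were above 0, led by Tie1 at 1.40 (camera adjusted p = 0.805). Of 16 blood endothelial and blood-brain barrier genes 9 were above 0 and 0 were called, and 2, Selp at -3.03 and Spock2 at -3.26, were lower when adjusted over the list alone (camera adjusted p = 0.841). The 11 genes of VEGF ligands, receptors and processing had a median of -0.08, with Flt1, the receptor VEGFR1, at -0.98 and, without eGFP 2, at 0.27 (camera adjusted p = 0.841). Of 12 VEGF and ERK response genes, the signalling inhibitors Spred1 and Spry1 stood at -2.19 and 1.80 (camera adjusted p = 0.841). The valve and collecting vessel list (14 genes) included Bmp4 at -2.57, the junction list (15 genes) Jam3 at -2.66 and Ctnnb1 at -1.05, the matrix list (25 genes) Fbln5 at 2.82 and Loxl2 at -1.70, the integrin list (18 genes) Itga5 at 2.30, and the guidance list (21 genes) Slit3 at 1.43. Each of these 5 lists had a camera adjusted p of 0.841.

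Among genes of antigen presentation, Nlrc5 (chromosome 8, 94434356 to 94527272), the transactivator of MHC class I genes, rose from 1004 ± 835 normalised counts in eGFP to 8028 ± 5058 in mVEGF-C libraries (n = 2 each), a log2 fold change of 3.14 with an SE of 0.88 (limma, adjusted p = 0.0242). It was the 1 called member of 15 antigen presentation genes, of which 10 had fold changes above 0 and 3 were higher when adjusted over the list alone (camera adjusted p = 0.356). Without eGFP 2 it was not called (adjusted p = 0.846), nor without mVEGF-C 1 (0.39), without trend (0.226) or with the corrected spread (0.204). Of 22 interferon response genes 14 had fold changes above 0, and 1 was called higher, against 2 when adjusted over the list alone (camera in limma, adjusted p = 0.261, and adjusted p = 0.883 with an estimated correlation).

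Icam1 (chromosome 9, 21015985 to 21028817), an adhesion molecule for leukocytes, fell from 709 ± 236 normalised counts in eGFP to 30.3 ± 11.1 in mVEGF-C libraries (n = 2 each), a log2 fold change of -4.51 with an SE of 1.28 (limma, adjusted p = 0.0255). It was the only called member of the 16 trafficking and chemokine genes, of which 7 had fold changes above 0 and 3 were lower when adjusted over the list alone (camera adjusted p = 0.728), and of the 15 NF-kB and inflammatory genes, of which 7 were above 0 and 1 was higher and 1 lower over the list alone (camera adjusted p = 0.841). The call was lost in edgeR (adjusted p = 0.0579), and without eGFP 1 (0.449), eGFP 2 (0.657) or mVEGF-C 1 (0.0938).

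Of 9 Notch pathway genes, 2 targets of Notch signalling that encode transcriptional repressors were lower. Heyl (chromosome 4, 123233556 to 123249875) fell from 315 ± 197 to 17.3 ± 22.9 (log2 fold change -5.07, limma adjusted p = 0.0103) and Hey1 (chromosome 3, 8663359 to 8667256) from 269 ± 124 to 11.5 ± 8.71 (-4.56, limma adjusted p = 0.0303). The other 7 were not called. Of the 9 genes 6 had fold changes above 0, with a median of 0.78 and a mean of -0.18, and the list did not pass (camera adjusted p = 0.841). Both calls were lost in edgeR (adjusted p = 0.0934 and 0.064), and each was lost when any library but mVEGF-C 2 was left out (0.19 to 0.908 for Heyl without eGFP 1 and eGFP 2, 0.306 and 0.995 for Hey1, and 0.355 and 0.169 without mVEGF-C 1, where the log2 fold change of Heyl was -3.04). TGF-beta and BMP genes (22 tested, camera adjusted p = 0.805) included Smad5 at 1.24 and Acvrl1 at -2.50, Wnt genes (11 tested, 0.872) Lrp6 at 1.27 and Axin1 at 2.62, and the unfolded protein response (17 tested, 0.728) Calr at 1.27 and Dnajb9 at 2.04. No member of these 3 lists was called.

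Subunits of the respiratory chain encoded in the nucleus gave 3 called decreases. The cytochrome c oxidase subunits Cox5b (chromosome 1, 36691449 to 36693681) and Cox6b1 (chromosome 7, 30616861 to 30626151) had log2 fold changes of -5.77 and -4.94, and Ndufa4 (chromosome 6, 11900292 to 11907497) of -4.40 (limma, adjusted p = 0.00197, 0.0124 and 0.0401). Cox5b and Ndufa4 were each at 0 in 1 mVEGF-C library. Of 28 such genes tested 15 had fold changes above 0, with a median of 0.19, and the list did not pass (camera adjusted p = 0.728). Without eGFP 2 none of the 3 was called (adjusted p of 0.402 to 0.999), nor without eGFP 1 (0.126 to 0.459); without mVEGF-C 2 Cox5b and Cox6b1 were not (0.131 and 0.265, at log2 fold changes of -3.77 and -2.98), without mVEGF-C 1 Ndufa4 was not (0.395), and in edgeR Cox6b1 and Ndufa4 were not (0.0957 and 0.0737). Ndufa4 was also not called with a pseudocount of 5 (0.0721), quantile normalization (0.107) or robust eBayes (0.0625).

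Among mitochondrially encoded transcripts, the large ribosomal RNA mt-Rnr2 was the 1 called of 15, at 3291130 ± 5008 against 2795280 ± 32374 normalised counts (n = 2 each), a log2 fold change of 0.24 with an SE of 0.02 (limma, adjusted p = 2.81e-29). Its call was lost without trend (adjusted p = 0.971) and in DESeq2 (0.945), and quantile normalization, which gives the most abundant gene 1 value in every library, set its difference to 0. The list had the lowest p of all lists (camera p = 0.00453, adjusted p = 0.145; adjusted p = 0.883 with an estimated correlation), with 9 members above 0. The nuclear long noncoding RNA Malat1 was called at 0.23 among 3 such RNAs (limma, adjusted p = 0.00146). It was not called without trend, in edgeR or in DESeq2 (0.972, 0.136 and 0.946), nor without mVEGF-C 2 (0.435, at 0.15), with robust eBayes (0.426) or with the libraries rescaled to 1 total or the upper quartile (0.132 and 0.0934), and quantile normalization set its difference to 0 too.

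Of the other programmes, the 56 cytosolic ribosomal protein genes had a median fold change of 0.02 with 0 called (camera adjusted p = 0.841), with Rps6 at 1.54. Of 15 cell cycle genes 12 were below 0, with Mcm5, a replication licensing gene, at 3.89 and higher when adjusted over the list alone, and Cdk1 at -3.42 (camera adjusted p = 0.774). Glycolysis and hypoxia genes (18 tested, 0.841) included Gapdh at 1.38 and Ldha at -3.25. Fatty acid and lipid genes (17 tested, 0.805) included Fabp5 at -3.76 and Acaa2 at -3.49, both lower when adjusted over the list alone and neither called; this was the 1 list that passed the mixed fry test (adjusted p = 0.0345), while its directional fry adjusted p was 0.179. Immediate early and dissociation genes (16 tested, 0.811) included Atf3 at -3.95 and Fosl2 at 2.72, which were lower and higher over the list alone. Of 12 senescence and p53 genes 4 had fold changes above 0, and Igfbp5, a secreted binding protein of insulin-like growth factors, was called at 0.62 (limma, adjusted p = 0.0151; camera adjusted p of the list 0.983). Its eGFP values were 140594 and 51757, on either side of both mVEGF-C libraries, and its fold change was -0.10 without eGFP 2 and 1.34 without eGFP 1. The call was lost without mVEGF-C 1 or mVEGF-C 2 (limma, adjusted p = 0.242 and 0.169), with robust eBayes (0.162), with the libraries rescaled to 1 total or the upper quartile (0.0621 and 0.0566), in edgeR (0.326) and in DESeq2 (0.885).

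Among markers of other cells, 1 list member rose and 1 fell. Fmod (chromosome 1, 134037254 to 134048277), a matrix proteoglycan of fibroblasts, rose from 3096 ± 3014 to 14530 ± 967 normalised counts (n = 2 each), a log2 fold change of 2.69 with an SE of 0.68 (limma, adjusted p = 0.00729). It was the 1 called of 16 meningeal fibroblast markers, of which 12 were above 0 with a median of 0.74 (camera in limma, adjusted p = 0.237, and adjusted p = 0.883 with an estimated correlation); over the list alone 1 was higher and 1 lower. With the corrected spread Fmod was still called (adjusted p = 0.00568). Its SE there was 0.571, the value of the most abundant bin and below the 0.68 of the main fit. That call therefore says nothing of how Fmod stands up to the selection. Fmod was not called in DESeq2 (adjusted p = 0.147), nor without eGFP 2, mVEGF-C 1 or mVEGF-C 2. With 1 library left out its log2 fold change lay between 1.47 (without eGFP 2) and 3.91. Ttr (chromosome 18, 20665280 to 20674321), the thyroxine carrier abundant in choroid plexus, fell from 11766 ± 11057 to 668 ± 221, a log2 fold change of -3.76 with an SE of 0.89 (limma, adjusted p = 0.00306), with 3947 in eGFP 1 and 19584 in eGFP 2. Without eGFP 2 it was not called (adjusted p = 0.999, log2 fold change -2.60). It was the 1 called of 8 Schwann and neural markers (camera adjusted p = 0.983), of which 4 had fold changes above 0 and 1 was higher and 1 lower over the list alone.

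The remaining marker lists had no called member. Macrophage and dendritic cell markers (11 tested, camera adjusted p = 0.841) included Laptm5 at 2.52 and Fcer1g at -2.05. Mural markers (6 tested, 0.728) included Notch3 at -2.74 and Abcc9 at -1.07, lymphocyte markers (5 tested, 0.841) Cd3g at -1.81 and Cd4 at -1.44, and bone and cartilage markers (6 tested, 0.841) Mmp13 at -3.46, which was lower over the list alone, and Dmp1 at 2.18. The other lists had too few members for a test: 3 arachnoid markers, with Abcg2 at -0.92 (0.20 without eGFP 2) and Dpp4 at -1.03 (0.52 without mVEGF-C 2), 4 neutrophil and mast cell markers, with Cxcr2 at 2.54 and Lcn2 at 1.15, and 3 erythroid and platelet markers, with Hba-a2 at -1.65 and Epb42 at -1.19.

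**Figure D4:**
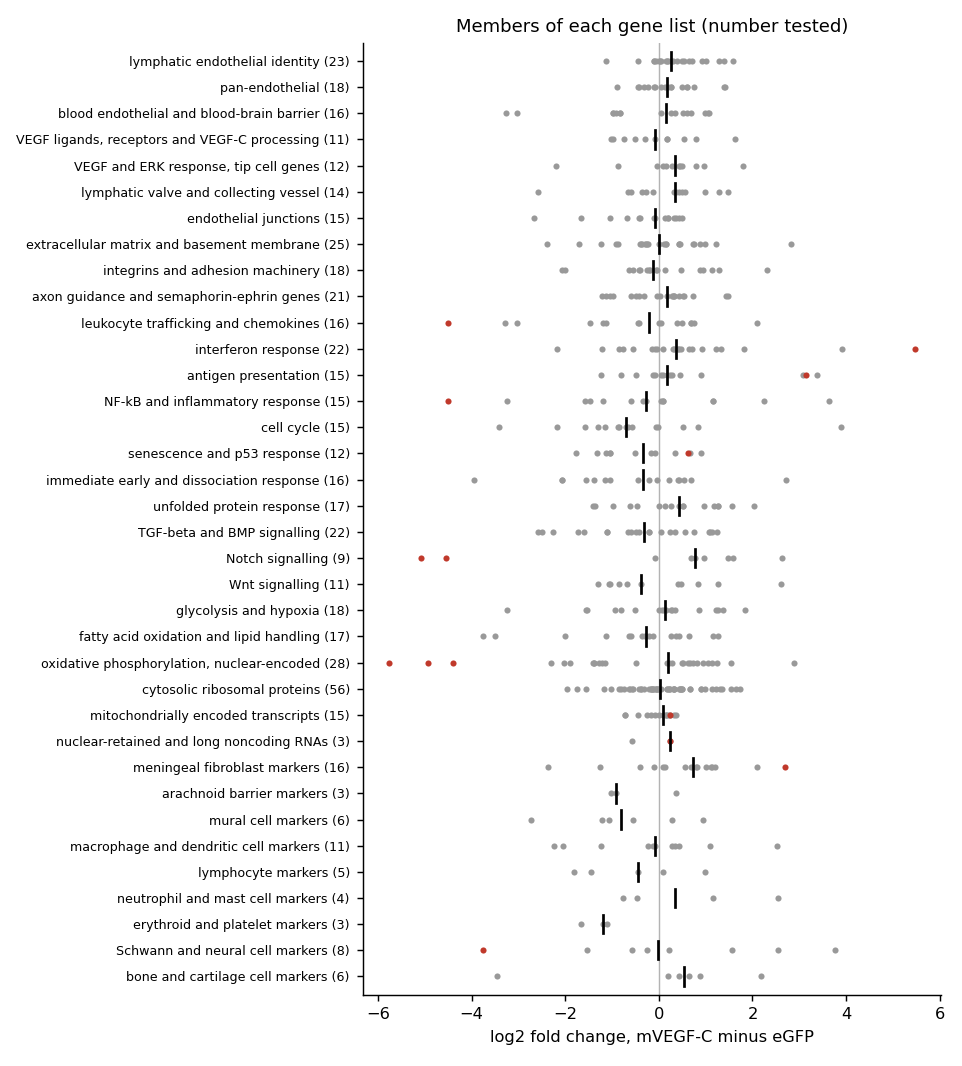
Each point is a tested member of a list (number in brackets), placed by its log2 fold change, mVEGF-C minus eGFP. Red points are called genes and black ticks the list medians, which lie between -1.19 and 0.78.

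Of the 32 lists tested, camera passed 0 at an adjusted p under 0.05, and 4 had an unadjusted p under 0.05: mitochondrially encoded, lymphatic identity, meningeal fibroblast and interferon genes. With an estimated correlation the lowest adjusted p was 0.883, fry in its directional form gave 0.179, and camera by ranks passed 0 lists. Without eGFP 1 the mitochondrial and the fibroblast list passed, and without eGFP 2 the mitochondrial and the lymphatic identity list. Those fits kept the preset correlation of 0.01, whereas the estimate for the fibroblast list over all libraries was 0.357. The SE of mt-Rnr2 in them was 0.012 and 0.010. Over all libraries the mitochondrial list had a median of 0.084 and a mean of -0.04. For the fibroblast and mitochondrial lists these passes therefore do not show that the list moved as a whole. These reasons do not cover the lymphatic identity list, with a median of 0.27, a mean of 0.36 and an estimated correlation of 0.056. Its pass rests on a fit with 1 eGFP library. Over all libraries its camera adjusted p was 0.217, and 0.883 with the estimated correlation. Of the 13 called list members, 1 was still called by eBayes without trend. With the corrected spread Fmod alone was, at a smaller SE than in the main fit. In 11 of the 32 lists the median, the mean and the camera statistic differed in sign, among them Notch (median 0.78, mean -0.18) and nuclear oxidative phosphorylation (median 0.19, mean -0.58). The other 9 were blood endothelial, VEGF ligands and receptors, matrix, integrin, senescence, Wnt, glycolysis, mitochondrially encoded and neural genes.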

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

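Of the alternatives, 3 were chosen after the data were seen: the corrected spread, the eGFP limit for both groups and mitochondrial rows left out. The counts of 75 higher and 119 lower genes stayed within 1.5 times under both other pseudocounts, both other filters, the 3 scalings, robust eBayes, voom, the fold change limit and mitochondrial rows left out (62 to 99 higher, 108 to 126 lower). Without trend they were 15 and 26. DESeq2 called 289 and 329, of which 68 and 119 are shared with limma, and edgeR 79 lower, of which 72 are shared. An adjusted p under 0.1 gave 121 and 184. The eGFP limit for both groups gave 145 higher among 7970 genes, and the corrected spread gave 6 and 8. Leaving out 1 library gave 5 to 104 higher and 0 to 188 lower genes. The group left with 1 library is then assumed to vary like the other, and without either eGFP library that is the wider spread of the mVEGF-C pair (SD of the log2 differences 1.70, against 1.31 in the eGFP pair). At an unadjusted p under 0.05, 203 and 196 genes remained without eGFP 2. Camera passed 1 list with voom weights (mitochondrial) and 0 to 2 with 1 library left out. The causes were not tested.

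Replicate numbers did not pair the samples: the deviations of same-numbered libraries correlated at 0.00013. With the replicate number as a block, 74 genes were higher and 129 lower and 0 lists passed; of the named genes called, Malat1 and Igfbp5 then missed the threshold (limma, adjusted p = 0.0548 and 0.0733). Among the 88 named genes, the called gene Igfbp5 reversed without eGFP 2, to -0.10, and ranged to 1.34 with 1 library left out. A further 5, not called, changed sign with 1 library left out: Flt4 (-0.08 without eGFP 1), Flt1 and Abcg2 (0.27 and 0.20 without eGFP 2), Pdpn (0.11 without mVEGF-C 1) and Dpp4 (0.52 without mVEGF-C 2). Some named genes not called in the main fit gained a call elsewhere: 12 in DESeq2, 5 with the eGFP limit for both groups and 1 with quantile normalization. No scaling moved the median fold change of all genes by over 0.1 (-0.10 to 0.05 over all alternatives). The lowest recovered depth was 25610683 reads, and the spread between the 2 libraries of a group was far above counting noise (chi-square per degree of freedom of 457.8 and 520.7).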

Other observations

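The genes of this paragraph and the next were chosen after their values were seen. They are single genes outside the fixed lists, and no group was tested through them. Oasl1, an interferon-induced gene of the oligoadenylate synthetase family, had 6.04 ± 8.54 normalised counts in mVEGF-C and 195 ± 36.0 in eGFP libraries (log2 fold change -5.75, limma adjusted p = 0.00206), and H2-T22, a non-classical MHC class I gene with close paralogs, had 92.8 ± 52.7 against 2400 ± 1127 (-4.72, limma adjusted p = 0.00741). Tomm5, a subunit of the translocase of the outer mitochondrial membrane, stood at -5.89, the mitochondrial ribosomal protein gene Mrpl47 at -4.97 and Opa3 at -4.76 (limma, adjusted p = 9.35e-04, 0.0115 and 0.0172).

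Sema3e, a class 3 semaphorin that signals through plexin D1, had 1492 ± 31.1 normalised counts in mVEGF-C and 89.7 ± 39.1 in eGFP libraries (log2 fold change 4.11, limma adjusted p = 0.0370). Optc, a small leucine-rich proteoglycan like Fmod, stood at 4.43 (0.0342). Extracellular superoxide dismutase, Sod3, stood at -5.33 (0.00331). Values with ± are means and SDs of 2 libraries. Of the 8 genes of these paragraphs, 0 were called without eGFP 1 (limma, adjusted p of 0.0846 to 0.513), without eGFP 2 (0.210 to 0.999) or with the corrected spread (0.119 to 0.409), and without trend Tomm5 alone was. Without mVEGF-C 1, Optc and Tomm5 were called, and the log2 fold changes of Mrpl47 and Opa3 were -3.13 and -2.96. Without mVEGF-C 2, Optc and Sema3e were not called (0.189 and 0.0691), and edgeR did not call Opa3, Optc and Sema3e (0.115, 0.0543 and 0.0755).

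The tests on depth, trend and scaling below were chosen after their results were seen; those on selection, on the genes free of the limits and on choroid plexus markers were written before. The first pattern is the set of 194 called genes. The values argue against depth, since the groups overlapped and mVEGF-C libraries held 1.04 times the reads of eGFP libraries. Selection on replicate agreement stays open: 50 tables simulated with no group difference gave a median of 16 calls with normal noise and, in a run added afterwards, 102.5 with heavier-tailed t noise of 3 degrees of freedom (highest 41 and 169). The bound set beforehand for this cause was a median of at least 50% of the called genes. It was missed with normal noise and met with t noise. The bound for ruling the cause out was met in neither run. An effect of VEGF-C stays open too and could not be tested: the test written beforehand, the share of genes passing the limits under every pairing of the libraries whose 2 highest libraries were 1 group (31.9% of 6257, against 31.9% and 35.8% for the other 2 pairings), decides nothing, since only 4 of the 194 called genes are among them. The full limma fit called 194 genes for the real grouping and 0 for each of the other 2, which the limits bound by construction, and 3 groupings are too few to judge chance.

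The second pattern is abundant genes called at small fold changes: mt-Rnr2, Malat1, Igfbp5, Srrm2 and Fstl1, the 5 called genes with an absolute log2 fold change under 2. Without the trend 0 of the 5 were called at the same fold changes. The SE of mt-Rnr2 went from 0.02 to 0.87 and that of Srrm2 to 0.88. With SEs of that size no fold change under 2 could be called, so this outcome was fixed in advance and is no test of the cause. The SEs show only that these calls rest on the small spread that the trend, fitted where few genes lie, gave these genes. With the libraries rescaled to 1 total or to the upper quartile, 2 of the 5, mt-Rnr2 and Srrm2, were still called, and mt-Rnr2 stood at 0.15 and 0.16, so scaling may account for part of the pattern. A difference between the groups stays open and was not tested for these genes.

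The third pattern is the lower Ttr in mVEGF-C libraries, for which RNA of choroid plexus epithelium in the eGFP libraries is a candidate source. The gate for CD31 and podoplanin need not have kept such RNA out, since meningeal fibroblast markers were abundant too (median level 6894). Of 26 other choroid plexus markers 12 had a row, 6 of them below 0 and 0 called, with a median log2 fold change of 0.052 (SE of the median 0.403). The most abundant were Aqp1 at 21478, Igf2 (also on the meningeal fibroblast list) at 12727 and Atp1b1 at 2734 normalised counts. All 12 were also above 0 in the mVEGF-C libraries. The median fold change met the bound set beforehand for ruling the source out, a median above -1 by more than 2 SE. After the result was seen that bound was judged wrong, because the median level of the 12 in mVEGF-C libraries was 1422 against a Ttr excess of 11098, so the markers' own level could hide a small share of choroid plexus RNA, and that source and a change in the sorted cells cannot be told apart here.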
